A study of Mus musculus with 2 samples.

How the data were processed

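Total RNA sequencing of granulocyte-monocyte progenitors was analysed from 2 libraries of 1 group. Per the labels, RNA was depleted of ribosomal RNA, libraries were made with a ScriptSeq low-input kit from 100 ng of RNA, and the size range was 200 to 712 for replicate 1 and 200 to 1000 for replicate 2, with no unit given. The deposited files give expected counts per gene and transcript, in which reads shared among features are split by an estimator. The deposited files also give TPM, scaled over all features in the file, and FPKM, together with posterior mean counts, posterior mean TPM and bounds of a credibility interval. The deposited transcript tables give each transcript's percent of its gene. The deposited metadata name the assembly mm10 and the GENCODE annotation M4; the aligner and quantifier are not given in the sources used here. The mean fragment length implied by length minus effective length plus 1, over transcripts above 2000 nt, was 178 nt in replicate 1 and 214 nt in replicate 2. A difference in fragment length changes the effective length of short RNAs most, so TPM of small RNAs is less comparable between the libraries than CPM.

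Gene symbols, classes, coordinates and transcript sequences were taken from GENCODE M21, a later release on the same assembly, by identifier without version. Of 43346 annotated genes, 42462 were matched and 884 were not and carry no name here. The 26248 tRNA and 97 spike-in entries were left out of gene counts. Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3. Libraries were scaled by the trimmed mean of M values, with factors of 0.985 and 1.02. The biological coefficient of variation is the square root of the common dispersion of an intercept-only model on 12855 genes kept by filterByExpr. Ratios between libraries are log2 CPM with a prior count of 2. Tested on simulated data for 12855 genes with 200 changed, the spread came out as 0.116 where 0.1 was simulated and as 0.305 where 0.3 was simulated.

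Levels were compared as medians of log2(TPM + 1) over 28 gene lists fixed before the data were examined, as were the 7 contrasts and the alternatives named below. Log values understate differences of low genes. Snhg1 had no matching identifier. Some list members are not reported here by name. Genes named are members of those lists, the 20 protein-coding and the 10 genes of any class with the highest mean TPM, the 10 furthest apart in each direction between libraries among genes with a mean of at least 10 CPM, and 15 genes fixed for transcript shares. Genes outside this rule are named in the closing section only, and were chosen after their values were seen. List medians were set against 10000 random lists, drawn from genes at or above 0.1 TPM in either library for levels, and matched on mean expression in 50 bins for ratios. In 200 simulated lists of 10 genes, 7.0% lay outside the 95% range with no shift added, 73.0% with a shift of 0.25 and 100.0% with 0.5. GC content and length refer to each gene's leading transcript. Trends were fitted by lowess with a span of 0.3 in statsmodels 0.14.6, and nuclear copies of mitochondrial genes were found with BLAST 2.17.0 at 90% identity over at least 100 nt.

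Alternatives were other thresholds and pseudocounts, FPKM, posterior means, rescaled TPM, means in place of medians, lists without low members, DESeq2 1.42.0 size factors, other filters, and each library alone. With 1 group and 2 libraries, no gene was tested and no paired or group comparison was made.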

Results

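Total RNA was sequenced from granulocyte-monocyte progenitors, bone marrow cells that give rise to neutrophils and monocytes. The cells were primary cells of male C57BL/6J mice aged 5 to 6 weeks. The series holds 1 group of 2 biological replicates, each made from 100 ng of RNA depleted of ribosomal RNA. Replicate 1 held 49473848 and replicate 2 held 44260902 expected counts. No condition was compared, so the results are the level of each gene, the contrast between gene groups within each library, and the spread between the replicates. With 2 libraries no p-value is given. The labels name the libraries as separate biological replicates and tie both to 1 donor record, so the SD given with each mean describes these 2 libraries and may be partly technical. Small noncoding RNAs held most of the TPM. Levels of protein-coding genes are therefore given as deposited and, where stated, rescaled so that nuclear protein-coding genes alone make up the total. Counts of genes at or above 1 TPM use deposited TPM, and a gene below 1 TPM there can exceed 1 on rescaled TPM. Nuclear protein-coding genes held 19.07% of the TPM in replicate 1 and 22.84% in replicate 2. The SD of a deposited TPM includes that shift, so a small SD need not mean close agreement between the libraries. A count of 0 allows up to 3 counts, which is 0.0606 CPM (counts scaled to the library total) in replicate 1 and 0.0678 CPM in replicate 2. Such limits cover counting error only.

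Genes of the surface proteins that textbook gates for such cells use bear on which population was sequenced. All 4 genes of the proteins that textbook gates select for were expressed. The Fc receptor gene Fcgr3 was at 110 TPM ± 10.4 (SD, n = 2) and Cd34, a sialomucin of progenitors, at 56.3 TPM ± 6.78. Fcgr2b, a second Fc receptor of the same gate, was at 27.2 TPM ± 9.11, and Kit, the stem cell factor receptor, at 22.1 TPM ± 2.43. Of the 9 genes whose proteins are excluded, 8 were below 1 TPM in both libraries and 3 had 0 counts in both. Ly6a, which encodes the stem cell antigen Sca-1, had 0 counts. By counting error alone this allows up to 0.0343 TPM in replicate 1 and 0.0470 TPM in replicate 2. The upper bounds of its deposited credibility intervals were higher, at 0.188 and 0.287 TPM. The exception was Itgam, the integrin of mature myeloid cells, at 5.17 TPM ± 1.01. Ly6g, below 1 TPM as deposited, was at 5.09 in replicate 1 and 3.33 in replicate 2 on rescaled TPM. On log2(TPM + 1), the median of the selected genes exceeded that of the excluded genes by 5.27 ± 0.26 (SD, n = 2), with 5.08 in replicate 1 and 5.45 in replicate 2. With a pseudocount of 0.1 it was 8.26. Kit lies on chromosome 5 at 75574916 to 75656722 and Cd34 on chromosome 1 at 194938819 to 194961279 of mm10. Xist, the noncoding RNA of the inactive X, had 0 counts in both libraries, and the Y-linked genes Eif2s3y and Ddx3y were at 28.2 TPM ± 7.36 and 14.0 TPM ± 3.12.

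Primary granule genes were the most abundant of the fixed lists of lineage genes. Mpo, encoding myeloperoxidase, had the highest mean TPM of all nuclear protein-coding genes, at 2552 TPM in replicate 1 and 2288 TPM in replicate 2, where Eef1a1 was higher at 2572 TPM. Ctsg, encoding the serine protease cathepsin G, was at 1058 TPM ± 16.4 (SD, n = 2). On rescaled TPM, Ctsg was at 5487 in replicate 1 and 4682 in replicate 2. Elane, encoding neutrophil elastase, was at 763 TPM ± 58.7, and its neighbour Prtn3, encoding proteinase 3, at 280 TPM ± 31.0. Srgn, the proteoglycan core of secretory granules, was at 574 TPM ± 177. Ctsc and Prss57 were lower, at 21.4 TPM ± 2.52 and 17.8 TPM ± 3.66. Mpo lies on chromosome 11 at 87793581 to 87804413, and Elane and Prtn3 lie on chromosome 10, with Elane at 79886247 to 79888215 and Prtn3 at 79874476 to 79883174.

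Genes of later neutrophil granules and of mature neutrophils, taken as 1 list, had a lower median than the primary granule genes. Of 12 such genes, 11 reached 1 TPM in both libraries and 6 reached 10 TPM. The calcium-binding proteins S100a8 and S100a9 led, at 378 TPM ± 183 and 200 TPM ± 34.0 (SD, n = 2). The secondary granule genes Ngp, Camp, Ltf and Lcn2 were at 53.1 TPM ± 7.52, 39.5 TPM ± 9.81, 17.1 TPM ± 3.10 and 12.1 TPM ± 0.149. On rescaled TPM, Lcn2 was at 64.2 in replicate 1 and 52.7 in replicate 2. The gelatinase gene Mmp9 and the chemokine receptor gene Cxcr2 were near 2 TPM, at 2.21 TPM ± 0.184 and 2.14 TPM ± 0.410. The median of the primary granule list exceeded that of the late list by 5.62 ± 0.27 on log2(TPM + 1), far more than the replicates differed. The 6 NADPH oxidase genes, which encode the phagocyte's superoxide-generating complex, were all above 10 TPM, from 15.7 TPM ± 3.37 for Cybb to 36.9 TPM ± 2.87 for Ncf1.

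The transcription factors of granulocyte and monocyte progenitors were all detected, 12 of 12 at 1 TPM or more in both libraries. Myb, required for progenitor growth, was highest at 127 TPM ± 20.5 (SD, n = 2). The zinc finger gene Zeb2 was at 40.7 TPM ± 2.94. Irf8, which favours the monocyte and dendritic fates, was at 39.3 TPM ± 1.23, and Gfi1, which favours the neutrophil fate, at 13.2 TPM ± 0.382. Spi1, encoding PU.1, was at 27.1 TPM ± 0.438, and on rescaled TPM at 144.0 in replicate 1 and 117.5 in replicate 2. Cebpe and Cebpa were at 13.04 TPM ± 0.672 and 8.08 TPM ± 1.03, and Klf4, a factor of monocyte differentiation, was lowest at 1.73 TPM ± 0.651. Irf8 lies on chromosome 8 at 120736358 to 120756694 and Spi1 on chromosome 2 at 91082390 to 91115756.

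Genes of stem and multipotent progenitor cells had a lower median than these factors. Of 10 such genes, 4 reached 1 TPM in both libraries, and Fgd5 had 0 counts in both. On rescaled TPM, Flt3, Hlf and Procr also exceeded 1 in both, with Flt3 at 4.83 in replicate 1 and 7.53 in replicate 2. Cd48, an adhesion protein kept by committed progenitors, was highest at 33.6 TPM ± 9.15 (SD, n = 2). Hoxa9 was at 4.53 TPM ± 1.71 and Meis1 at 3.58 TPM ± 0.785. The stem cell genes Hlf, Procr and Mecom were at 0.510 TPM ± 0.0990, 0.295 TPM ± 0.0354 and 0.175 TPM ± 0.0495. Procr had 15 counts in replicate 1 and 41 in replicate 2. The median of the myeloid factors exceeded that of the stem cell genes by 2.94 ± 0.19 on log2(TPM + 1) and that of B cell genes by 3.83 ± 0.04. The B cell difference has a floor, because the B cell median was 0 in both libraries. It was 7.06 with a pseudocount of 0.1 and 2.20 with members below 0.1 TPM in both libraries left out.

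Monocyte genes were expressed alongside those of neutrophil granules. Ly6c2, the surface antigen of inflammatory monocytes, was at 490 TPM ± 156 (SD, n = 2), the coagulation factor gene F13a1 at 102 TPM ± 19.5 and the chemokine receptor gene Ccr2 at 30.3 TPM ± 5.95. Csf1r, the receptor of macrophage colony-stimulating factor, was at 7.57 TPM ± 1.75. Dendritic cell genes were low: 7 of 10 were below 1 TPM in both libraries. The highest, the class II gene H2-Ab1, was at 4.64 TPM ± 0.545. On rescaled TPM, Cd74, H2-Aa and H2-Eb1 also exceeded 1 in both libraries. The monocyte median exceeded the dendritic median by 2.73 ± 0.07 on log2(TPM + 1). The size depends on the scale, with 5.06 at a pseudocount of 0.1 and 4.41 on rescaled TPM.

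Genes of eosinophils, basophils and mast cells were present at low to moderate levels. Hdc, the histidine decarboxylase gene, was at 31.2 TPM ± 1.92 (SD, n = 2), the mast cell carboxypeptidase gene Cpa3 at 22.0 TPM ± 6.26, and Prg2, encoding eosinophil major basic protein, at 18.2 TPM ± 1.27. Mcpt8 and Ms4a2 were at 9.29 TPM ± 4.00 and 8.13 TPM ± 0.163. Gata2 was at 1.25 TPM in replicate 1 and 0.73 TPM in replicate 2. Of the 11 genes, 7 reached 1 TPM in both libraries.

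Genes of other lineages were mostly near 0. Erythroid genes had a median of 0.190 TPM ± 0.0707 (SD, n = 2), with Car2, a carbonic anhydrase, highest at 4.30 TPM ± 1.78. Hba-a1 and Hba-a2 share nearly all of their sequence, so the split between them is uncertain; Hba-a2 was at 1.19 TPM in replicate 1 and 3.77 TPM in replicate 2. Of 9 megakaryocyte genes, 8 were below 1 TPM in both libraries, and Itga2b was at 3.15 TPM ± 0.332. The erythroid median exceeded the megakaryocyte median by 0.24 ± 0.10 on log2(TPM + 1). With members below 0.1 TPM in both libraries left out, that difference turned to -0.40 ± 0.16, so its direction rests on genes near 0. Of 10 B cell genes, the 2 detected were Ighm at 26.5 TPM ± 3.66 and Cd79b at 6.06 TPM ± 1.94, while Cd79a, Pax5, Ebf1, Rag1 and Ms4a1 had 0 counts in both libraries. Vpreb1 had 55 counts in replicate 1 and 0 in replicate 2. Of 12 T and NK cell genes, the granule membrane gene Nkg7 was the only one detected, at 26.9 TPM in replicate 1 and 53.2 TPM in replicate 2. All 10 stromal and endothelial genes were below 1 TPM in both libraries, with Pdgfrb highest at 0.805 TPM ± 0.120. Pdgfrb had 542 counts in replicate 1 and 514 in replicate 2, and was at 3.84 ± 0.0851 on rescaled TPM.

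The cells expressed genes of DNA replication and mitosis. All 12 S phase genes and all 12 mitosis genes reached 1 TPM in both libraries. Pcna, the replication clamp, was at 142 TPM ± 23.5 (SD, n = 2) and the helicase gene Mcm6 at 95.2 TPM ± 14.7. Top2a was at 146 TPM ± 19.6, Cdk1 at 70.0 TPM ± 2.05 and Mki67 at 61.7 TPM ± 12.7. Among the inhibitors of cyclin-dependent kinases, Cdkn1b and Cdkn2c were at 8.09 TPM ± 0.962 and 6.83 TPM ± 1.58, Cdkn1a was at 0.470 TPM ± 0.240, and Cdkn2a and Cdkn2b had 0 counts in both libraries. The S phase median exceeded that of the inhibitors by 4.72 ± 0.35 on log2(TPM + 1), and by 2.72 ± 0.14 with members below 0.1 TPM in both libraries left out. The 5 linker histone genes, whose mRNAs largely lack poly(A) tails, ranged from 157 TPM ± 19.0 for Hist1h1e to 456 TPM ± 11.5 for Hist1h1a.

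**Figure D1:**
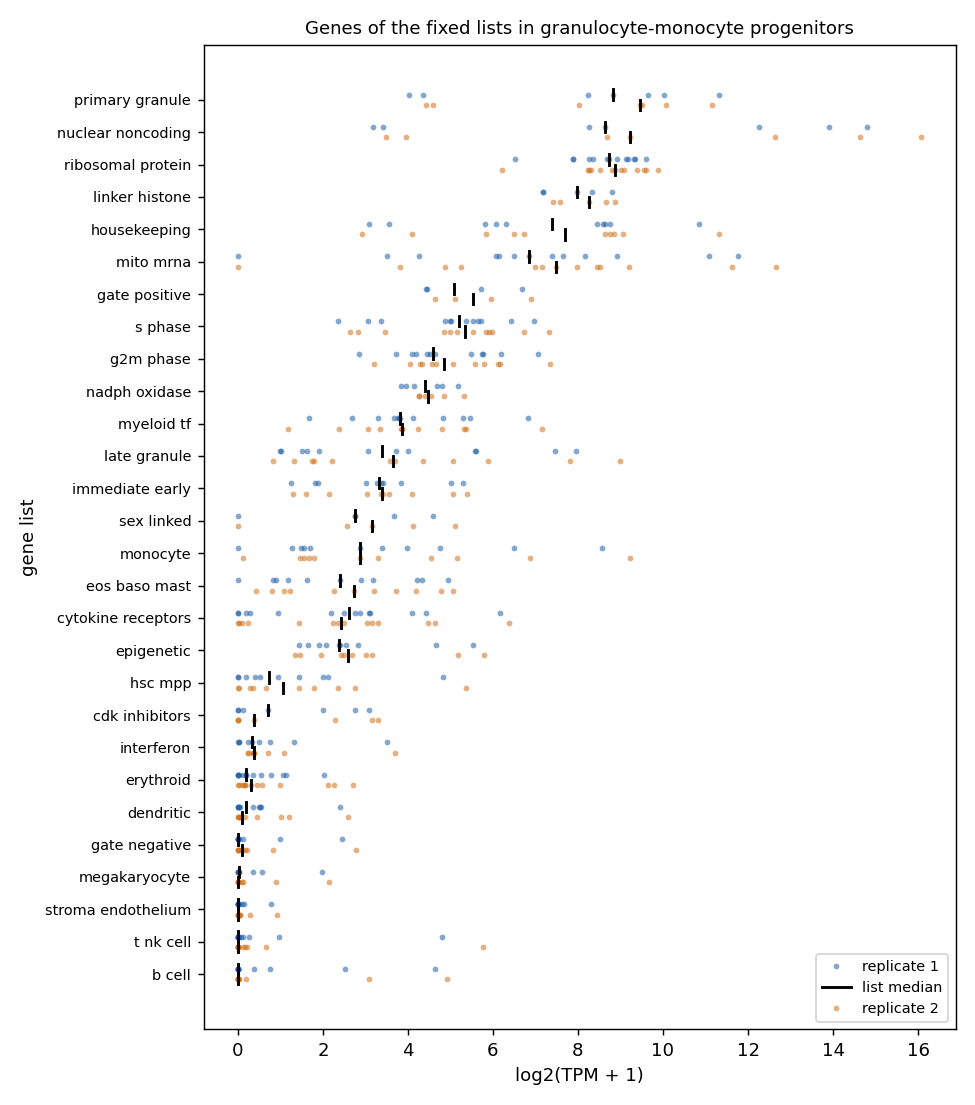
Each point is 1 gene of a fixed list in 1 library, on the log2(TPM + 1) axis, with replicate 1 in blue above replicate 2 in orange and black bars at each library's list median. Primary granule genes have the highest list medians, 8.81 in replicate 1 and 9.45 in replicate 2, and the B cell, T and NK cell and stromal lists lie at or near 0.

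Of 14 cytokine receptor genes, 9 reached 1 TPM in both libraries. Csf3r, the granulocyte colony-stimulating factor receptor gene, was at 18.7 TPM ± 3.61 (SD, n = 2), and Ifngr1 was highest at 76.6 TPM ± 8.00. Csf2rb was at 7.28 TPM ± 0.198, while Csf2rb2 was at 0.190 TPM ± 0.0283 and Flt3 at 0.92 TPM in replicate 1 and 1.72 TPM in replicate 2. Immediate early genes were all detected, with Jun at 39.6 TPM ± 1.70 and Fos at 31.9 TPM ± 0.615. Of 9 interferon-stimulated genes, 7 were below 1 TPM in both libraries. Among enzymes that modify DNA and histones, the maintenance methyltransferase gene Dnmt1 was at 49.98 TPM ± 6.27 and Ezh2 at 29.5 TPM ± 7.64, with the other 8 each below 10 TPM in at least 1 library. Among housekeeping genes, Actb was at 447 TPM ± 18.6 and Eef1a1 at 2205 TPM ± 519, and the 13 ribosomal protein genes had a median of 445 TPM ± 30.4.

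Set against 10000 random lists of the same size, 11 of the 28 list medians lay above the 95% range. Those above were the primary granule, myeloid factor, S phase, mitosis, NADPH oxidase and selected surface protein lists. They also held the housekeeping, ribosomal protein, mitochondrial mRNA, linker histone and nuclear noncoding lists. A place above the range is therefore not particular to lineage genes. Random lists were drawn from genes at or above 0.1 TPM while the fixed lists kept members at 0, so no list is placed below the range here. The late granule list lay at the 97.46th percentile and the monocyte list at 90.02, both inside the range. The eosinophil, basophil and mast cell list lay at 71.96, the cytokine receptor list at 77.84, the epigenetic list at 68.57 and the immediate early list at 94.28. Random lists of genes are not replicates, so these percentiles describe these libraries only.

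The 20 protein-coding genes of highest mean TPM held 12.0% of the protein-coding TPM in replicate 1 and 12.4% in replicate 2. After Mpo they included the translation factor Eef1a1, the chromatin-associated Ptma at 1748 TPM ± 63.8 (SD, n = 2), the chaperones Calr at 997 TPM ± 114 and Hspa8 at 897 TPM ± 109, Plac8 at 944 TPM ± 208, and Ctsg. Ribosomal protein genes such as Rpl36a and Rps3a1, and the histone genes Hist2h2aa1, Hist1h2ap and Hist1h4d, were also among them, and both families share reads with near-identical copies. Rescaled over nuclear protein-coding genes, Mpo was at 13386.5 TPM in replicate 1 and 10015.2 TPM in replicate 2.

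Nuclear protein-coding genes held 85.4% ± 2.17 (SD, n = 2) of the expected counts but 20.95% ± 2.67 of the TPM, which divides counts by effective length. Effective length depends on fragment length, most for short RNAs, so these TPM shares need not reflect numbers of molecules. Small noncoding RNAs held 8.28% ± 2.496 of the counts and 75.0% ± 3.59 of the TPM. Mitochondrial genes held 1.74% ± 0.224 of the counts, without reads assigned to their nuclear copies, so this share may be too low. For mt-Co3, the copy held 95.8% of the summed reads in replicate 1 and 93.9% in replicate 2. Spliceosomal snRNAs alone held 55.0% of the TPM in replicate 1 and 41.2% in replicate 2. Among the 10 genes of highest mean TPM were the U2 snRNA gene Rnu2-10, the signal recognition particle RNA copies Rn7s1 and Rn7s2, and Rn7sk, which regulates transcription elongation. Rn7sk was at 28528 TPM in replicate 1 and 69186 TPM in replicate 2, a difference of 0.69 on the log2 CPM scale. Rn7s1 and Rn7s2 fell by 1.07 on that scale from replicate 1 to replicate 2, and their reads are shared. The deposited credibility interval of Rnu2-10 in replicate 1, whose level is not given in the sources used here, ran from 4392 to 135524 TPM, so the value of a single copy is uncertain. The RNase P RNA gene Rpph1 was at 15423 and 25610 TPM and Malat1 at 398 and 601 TPM.

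In all, 9536 of 43346 annotated genes reached 1 TPM in both libraries, of which 8764 were protein-coding, and 5460 reached 5 TPM. Across these genes, Pearson's r of log2(TPM + 1) was 0.976 and Spearman's rho 0.959; genes are not independent replicates. The biological coefficient of variation was 0.265 over 12855 genes, 0.179 over the 8573 genes with a mean of at least 10 CPM, and 0.558 with no filter on low counts. Among the 8192 protein-coding genes at that level, the median absolute log2 ratio between the libraries was 0.181, and 38 genes differed by more than 1. Several of the genes furthest apart were pseudogenes or members of a pair of copies. Hist2h2aa2 was at 996 TPM in replicate 1 and 2.00 TPM in replicate 2, and its neighbour Hist2h2aa1 at 991 and 2052 TPM, while the 2 genes summed to 1987 and 2054 TPM. Phpt1, a histidine phosphatase gene, was at 1.15 TPM in replicate 1 and 10.9 TPM in replicate 2, and the protein-coding gene Gm14288 at 0.05 and 4.33 TPM. Expected counts of both genes were fractional in at least 1 library, so some of their reads were split with other features.

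**Figure D2:**
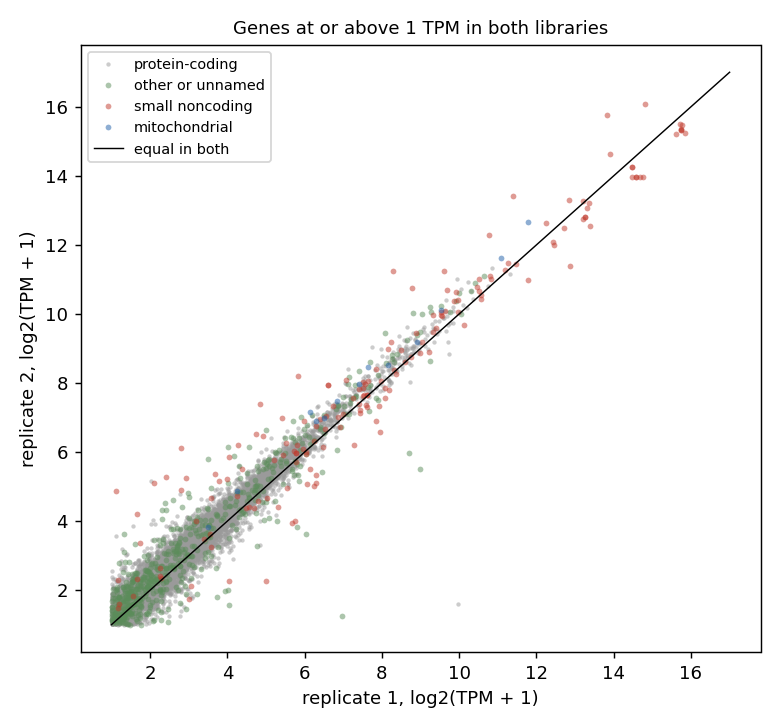
Each point is 1 of the 9536 genes at or above 1 TPM in both libraries, with log2(TPM + 1) in replicate 1 on the horizontal and in replicate 2 on the vertical axis, coloured by RNA class. Small noncoding RNAs, in red, reach the highest values, such as Rn7sk at 28528 and 69186 TPM.

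Of the 28 lists, 3 had a median ratio between the libraries outside the 95% range of 10000 expression-matched random lists, where 1.4 would be outside at the nominal rate. In simulated lists with no shift, 7.0% lay outside, which is above that rate. The primary granule list had a median log2 ratio of replicate 2 to replicate 1 of -0.28 against a range of -0.20 to 0.20, but its members were split. Mpo, Elane, Prtn3 and Ctsg were below 0, at -0.33, -0.48, -0.58 and -0.28, and Srgn, Prss57 and Ctsc above it, at 0.32, 0.11 and 0.09. The median TPM of the list, which is that of Srgn in both libraries, rose from 449 to 698 TPM. On rescaled TPM the list's median ratio of -0.23 lay at the edge of its range. The myeloid factor list had a median of -0.17 against a range of -0.16 to 0.18, with 9 of 12 members lower in replicate 2. The mitochondrial mRNA list had a median of 0.22 against a range of -0.17 to 0.19. This sets 1 library against 1 and has no replicate check. The ratio also followed the GC content of the transcripts: genes in the lowest quintile by GC had a median of 0.16 and those in the highest quintile -0.17. With a trend on GC removed, a step chosen after seeing the data, the myeloid factor and mitochondrial medians were -0.11 and -0.02, inside their ranges, and the primary granule median of -0.21 stayed outside. The nuclear noncoding median, inside its range at 0.14 before, was then 0.22, above its range of -0.20 to 0.12.

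**Figure D3:**
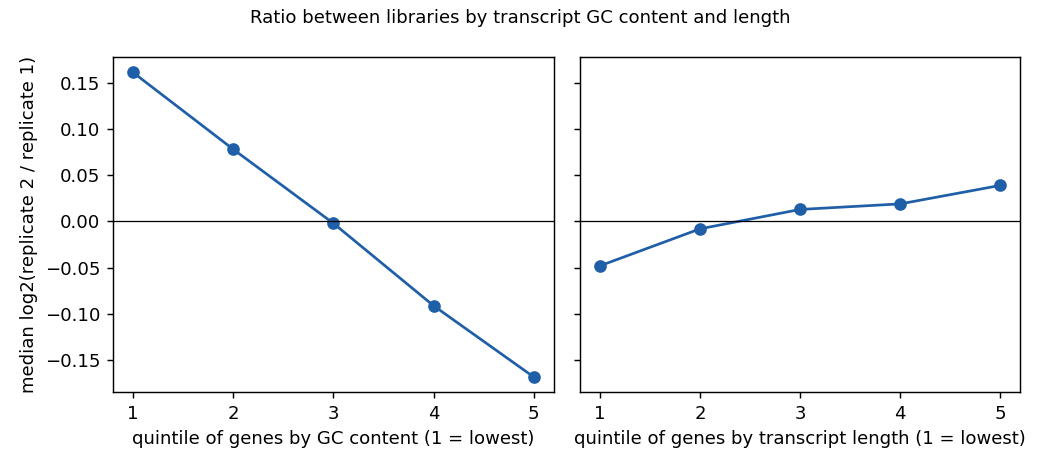
Median log2 ratio of replicate 2 to replicate 1 in quintiles of 8141 protein-coding genes, by GC content of the leading transcript on the left and by its length on the right. Over the quintiles by GC it runs from 0.16 to -0.17, and over those by length from -0.05 to 0.04.

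The leading transcript, the one with the highest mean share of its gene's TPM, was compared for 15 genes. Cebpa and Elane have 1 transcript each. For the other 13 genes, the leader was the same in both libraries for 9 and held at least 50% of the TPM in both for 8. Pkm was almost wholly 1 transcript, Pkm-201, at 95.4% ± 0.910 (SD, n = 2), and Irf8-201 held 95.8% ± 1.61 of Irf8. Ptprc, encoding CD45, was led by Ptprc-203 at 64.2% ± 3.64, Mpo by Mpo-203 at 75.3% ± 5.71 and Spi1 by Spi1-201 at 53.5% ± 0.334. The leader differed between libraries for Runx1, Gfi1, Kit and Cd44. For Kit it was Kit-201 at 47.8% in replicate 1 and Kit-204 at 43.6% in replicate 2. Meis1-201 held 87.5% of Meis1 in replicate 1 and 44.9% in replicate 2, where the gene was at 3.02 and 4.13 TPM.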

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

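The tests of explanations in this part were all chosen after values of single genes had been seen, and that on length also after a correlation of the ratio with length. Signals outside the main measurement came from 2 kinds of entry. The tRNA entries held 7 expected counts in replicate 1, above 3 counts, the limit that a count of 0 allows for a single feature, and 0 in replicate 2. These counts lay in 2 of the 26248 entries, and only 61 entries were counted as long enough for a fragment. Nearly all tRNA entries thus had little or no room for a read. The 884 genes without a name here held 119835 expected counts in replicate 1 and 110914 in replicate 2.

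Of the gene lists, 3 had median ratios between the libraries outside their random ranges, negative for the myeloid factors and for a primary granule list split into 4 lower and 3 higher members, and positive for mitochondrial mRNAs; a trend on transcript length was argued against, since it explained 0.814% of the variance of the ratio across genes, all 3 lists stayed outside with it removed, and the SD of the medians of the 15 lists with at least 5 members at a mean of 10 CPM or more was left at 0.988 of its former value, with a 95% bootstrap interval of 0.927 to 1.06. The GC trend explained 14.84% of the variance of the ratio across genes. Removing the GC trend left 0.671 of the former SD of list medians, with an interval of 0.593 to 1.04. GC content may thus account for part of the pattern and cannot be told apart from no effect on list medians by this interval. With the GC trend removed, the mitochondrial median moved from 0.22 to -0.02 and the myeloid factor median from -0.17 to -0.11, both within their random ranges, while the primary granule median of -0.21 stayed below its range of -0.17 to 0.12 and the nuclear noncoding median went from 0.14, inside its range, to 0.22, above its range of -0.20 to 0.12. With 1 group no biological difference between groups was tested, and a different share of other blood cells stays open too: 0 of 6 lists of other lineages met the criterion, but the megakaryocyte and B cell lists held too few counted members to test and only 2 lists had random ranges of a half-width below 0.5. Both conditions, that every list can be tested and has so narrow a range, were set after this outcome was seen, and without both the test would have argued against this explanation.

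The mitochondrial gene mt-Atp6 had 4800 expected counts in replicate 1 and 0 in replicate 2, and mt-Co2 was at 10.3 and 13.1 TPM beside mt-Co1 at 2173 and 3156 TPM. Reads shared with nuclear copies are a candidate explanation. The pseudogene Gm10925 on chromosome 1, at 24613974 to 24614651, matches mt-Atp6 at 100.0% over 678 nt and held 52846 and 62519 counts. Summed with their copies, mt-Atp6 and mt-Co2 differed between the libraries by at most 0.278 on the log2 scale, and the copies held at least 11.0 times the reads of the gene. Levels of mt-Atp6, mt-Co2, mt-Co3, mt-Nd3 and mt-Nd4l given singly are therefore uncertain.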

How the results depend on the processing

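Contrasts with lists near 0 moved with the pseudocount and scale; unless stated, the cause was not tested. Of 88 alternatives of 14 results, 16 leave out 1 library of a mean of 2, which stays within 1 SD by construction and says nothing about stability. Of the other 72, 33 left the value within tolerance, 38 moved it and 1 reversed it. Tolerance was the replicate SD for means, 1.5 times for counts, 3 equal digits for correlation and 2 for spread. With the GC trend removed, 2 lists lay outside their ranges in place of 3, of which 1 was shared. Rescaled TPM for genes detected and the removal of GC or length trends were chosen after seeing the data. Genes detected fell to 5460 at 5 TPM. Replicate correlation was 0.972 with a pseudocount of 0.1, 0.981 with no filter, 0.979 on CPM and 0.959 as Spearman's rho. Replicate spread was 0.558 with no filter, 0.228 for protein-coding genes and 0.179 for genes of at least 10 CPM. With a pseudocount of 0.1 the contrasts were 5.06 for monocyte minus dendritic, 3.88 and 7.06 for myeloid factors minus stem cell and minus B cell genes, 1.45 for erythroid minus megakaryocyte, 8.26 for the selected minus the excluded surface genes and 6.11 for S phase minus inhibitors. On FPKM these were 3.82, 3.51, 5.21, 0.57, 6.62 and 5.52, and on TPM rescaled over protein-coding genes 4.41, 3.71, 6.01, 0.88, 7.37 and 5.83. With members below 0.1 TPM in both libraries left out they were 2.35, 2.43, 2.20, -0.40, 4.78 and 2.72; the erythroid contrast reversed because its members near 0 were removed. With means of lists, primary minus late granule was 4.30, monocyte minus dendritic 2.90, myeloid factors minus stem cell and minus B cell genes 2.70 and 3.24, and S phase minus inhibitors 3.75. Posterior mean TPM gave 3.61 for myeloid factors minus B cell genes. Protein-coding genes held 20.95% of TPM against 85.4% of counts, since TPM divides by effective length. No paired analysis was possible because the series holds 1 group.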

Other observations

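The genes in this part were chosen after the data were seen. Of 11 Hoxa genes, the 2 detected at 1 TPM or more in both libraries were Hoxa9 and Hoxa7, at 4.53 TPM ± 1.71 and 1.89 TPM ± 0.382 (SD, n = 2), and no Hoxb, Hoxc or Hoxd gene was. Hoxb4 was at 0.455 TPM ± 0.00707. Of 12 Toll-like receptor genes, Tlr4 and Tlr2 were detected, at 3.58 TPM ± 1.52 and 2.43 TPM ± 1.27. Cebpd, encoding C/EBP delta, was at 17.7 TPM ± 0.870. Of 46 core histone genes of the Hist1 clusters, 43 were detected, and reads are shared among them.

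Among long noncoding RNAs, the host gene Gas5 was at 357 TPM ± 73.6 and Snhg5 at 70.6 TPM ± 19.4 (SD, n = 2). Gm26917, annotated as a long intergenic noncoding RNA, held 273785 expected counts in replicate 1 and 138782 in replicate 2. It was at 603 and 399 TPM, and its GC content was 69.1%. Which RNA its reads came from was not tested, so they are not evidence that a long noncoding RNA was expressed.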
